A study of Homo sapiens with 46 samples.

How the data were processed

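Chromatin immunoprecipitation sequencing (ChIP-seq) was done in H7, an established human embryonic stem cell line, at day 0 (ESC) and after differentiation to cardiac progenitor cells at day 4 (CPC). Of the 46 samples described, 22 were ChIP samples and 2 were inputs. The 18 mRNA-seq samples of day 4 and day 6 and the 4 Hi-C samples were not analysed here. The ChIP targets were RING1A and RING1B, the E3 ubiquitin ligases of Polycomb repressive complex PRC1, the doxycycline-induced FLAG-tagged mesoderm transcription factor MESP1, H3K4me3 and H3K27ac. Samples were grouped by the sample labels into 10 groups of 2 libraries each, 20 libraries in all, and the first run of a library and its resequencing counted as 1 library. The series text names a MESP1 knockout for H3K27ac while the sample labels name a RING1A knockout, and the sample labels were used.

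The files were 24 peak lists in hg19 coordinates. Trimming with Trim Galore, alignment with Bowtie2 and peak calling with MACS2 are listed in the submitters' processing notes, which also name HiC-Pro 2.11.1; versions of the other tools and read depths are not given in the sources used here. Peaks were called per library. In the 18 lists with 10 columns, the values deposited by the authors for each peak are a display score, a fold enrichment over local background (a ratio), and −log10 p and −log10 q, as MACS2 writes them. A list with 5 columns holds a deposited score that was read as 10 times −log10 p. Another 5 lists hold positions without peak values. These values are the authors' own and were used to describe, rank or filter peaks within a list. Depth per library is unknown, so no interval for read counting could be given, and precision is limited by the number of libraries.

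Calling thresholds differed between lists, which affects every count of present or absent regions. The lowest −log10 q was 1.31 in replicate 1 of RING1A in CPC and 2.01 in replicate 1 of H3K27ac in wild-type CPC. In replicate 2 of RING1A in MESP1-knockout CPC the lowest −log10 p was 3.00, and 1319 of its 3188 peaks had q below 0.05. The names of replicate 2 of RING1A in wild-type CPC and in ESC carry stricter q thresholds than either knockout list shows. Names of 3 lists do not mention removal of blacklisted regions (replicate 1 of RING1A in ESC, and replicate 1 of RING1B in ESC and in CPC). Names of the lists carry dates. Same-numbered wild-type and MESP1-knockout RING1A lists share dates, as do same-numbered ESC and CPC lists of RING1B and replicate 1 of RING1A in ESC and CPC. No date is shared between wild-type and knockout lists of H3K27ac, so genotype and date cannot be told apart there. The FLAG-MESP1 lists carry different doxycycline numbers and dates in their names. Nothing in the labels says that replicates came from separate cultures, so differences between them may be technical.

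Peaks on the 22 autosomes and X were kept, and peaks within 1 kb were merged in every list. Regions overlapped when they shared at least 1 bp. A consensus region was one called in both libraries of a group, and a region was lost or gained when no list of the other group overlapped it. Where a sample had several lists, the one named earliest in its description was used. Region strength was the mean rank of the authors' −log10 p over the libraries of a group, or of region width where a list had no peak value (RING1A in ESC, RING1A in wild-type CPC of the knockout comparison, and FLAG-MESP1). Within lists that had peak values, Spearman's rho between value and width over regions ranged from 0.468 to 0.811.

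With 2 against 2 lists there are 3 splits, so the smallest share of splits is 0.33 and no permutation of libraries can pass 0.05. Kept, lost and gained shares were therefore given as values, beside the overlap of replicates. Overlap of RING1A with RING1B was compared with 1000 circular shifts of the RING1B regions along each chromosome (one-sided, smallest possible p 0.001). Odds ratios were pooled over strata with the two-sided Cochran-Mantel-Haenszel test, with 95% intervals. The strata were overlap with H3K4me3 for RING1A at MESP1 sites, and 4 classes of region strength for losses and gains. Regions are the units of these tests, not replicates, and neighbouring regions are not independent, so the p-values describe these lists and are too small as statements about cultures. Benjamini-Hochberg adjustment was made over the 6 planned tests, and separately over 9 tests added after the lists were seen, which are the odds ratios at gained regions, the losses at H3K27ac regions and at regions absent from ESC, the H3K27ac gains and the H3K27ac loss at H3K4me3 regions. Shares of regions carry Wilson 95% intervals in the plots, which cover counting error over regions.

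The pooled odds ratio was tested on simulated data for the comparison of RING1A loss at MESP1 sites. In 200 simulations of 9000 regions with an odds ratio of 2 inside strength strata, the median estimate was 2.00, the interval held the true value in 92.0% and the share of false calls with no effect was 6.00%. Coverage was thus slightly below the nominal 95%. Simulated regions were independent, and the risk of loss within a stratum varied only with FLAG-MESP1, whose share fell across strata. Dependence between neighbouring regions and strength differences within a class were therefore not covered. In the data the FLAG-MESP1 share did not fall in this way, with 378, 420, 423 and 378 such regions from the narrowest to the widest class. The simulated link between FLAG-MESP1 and strength was thus not that of the data.

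The planned comparisons, their tests, the naming rule and most other settings were fixed before the data were examined, and those added later are named in the closing section. The other settings fixed beforehand were no merging, merging within 3 kb, an equal number of strongest regions in the compared lists, the stronger 50% of each list, an overlap of 50% of the shorter region, leaving out each library, other deposited lists of the same sample, averages over same-numbered pairs of libraries, other strata and other region universes. Equal numbers were taken by peak value where every compared list had one and by width otherwise. Regions were named by this rule: up to 5 regions per direction and comparison, strongest first. Coordinates are hg19 and 1-based. No hg19 gene annotation was used here, so regions carry no gene names, promoter counts were not made and the 18 gene lists drawn up beforehand were not tested. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.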

Results

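Peak lists of 20 ChIP-seq libraries, 2 per group, described where PRC1, MESP1 and active histone marks lay in ESC and CPC. The number of merged regions per list ranged from 6482 to 7135 for RING1A in ESC and from 10786 to 12164 for RING1A in CPC. RING1B lists held 12646 and 11357 regions in ESC and 7877 and 11163 in CPC. A separate RING1A experiment compared wild-type CPC, with 14061 and 15639 regions, and MESP1-knockout CPC, with 7305 and 2728. FLAG-MESP1 lists held 38396 and 26884 regions. H3K27ac lists held 32833 and 37216 regions in wild-type CPC and 32145 and 31034 in RING1A-knockout CPC, and H3K4me3 lists held 24099 and 24269. Read depth was unknown for each library.

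Replicate lists overlapped only in part. Of the regions of RING1A replicate 1 in ESC, 52.2% were found in replicate 2, and 41.0% in the opposite direction. In CPC the corresponding RING1A values were 66.4% and 61.3%, and in the wild-type libraries of the knockout experiment 66.4% and 58.5%. The MESP1-knockout lists shared 13.3% of the regions of replicate 1 and 49.1% of those of replicate 2. RING1B replicates shared 62.1% and 69.6% in ESC and 77.7% and 54.9% in CPC.

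**Figure D1:**
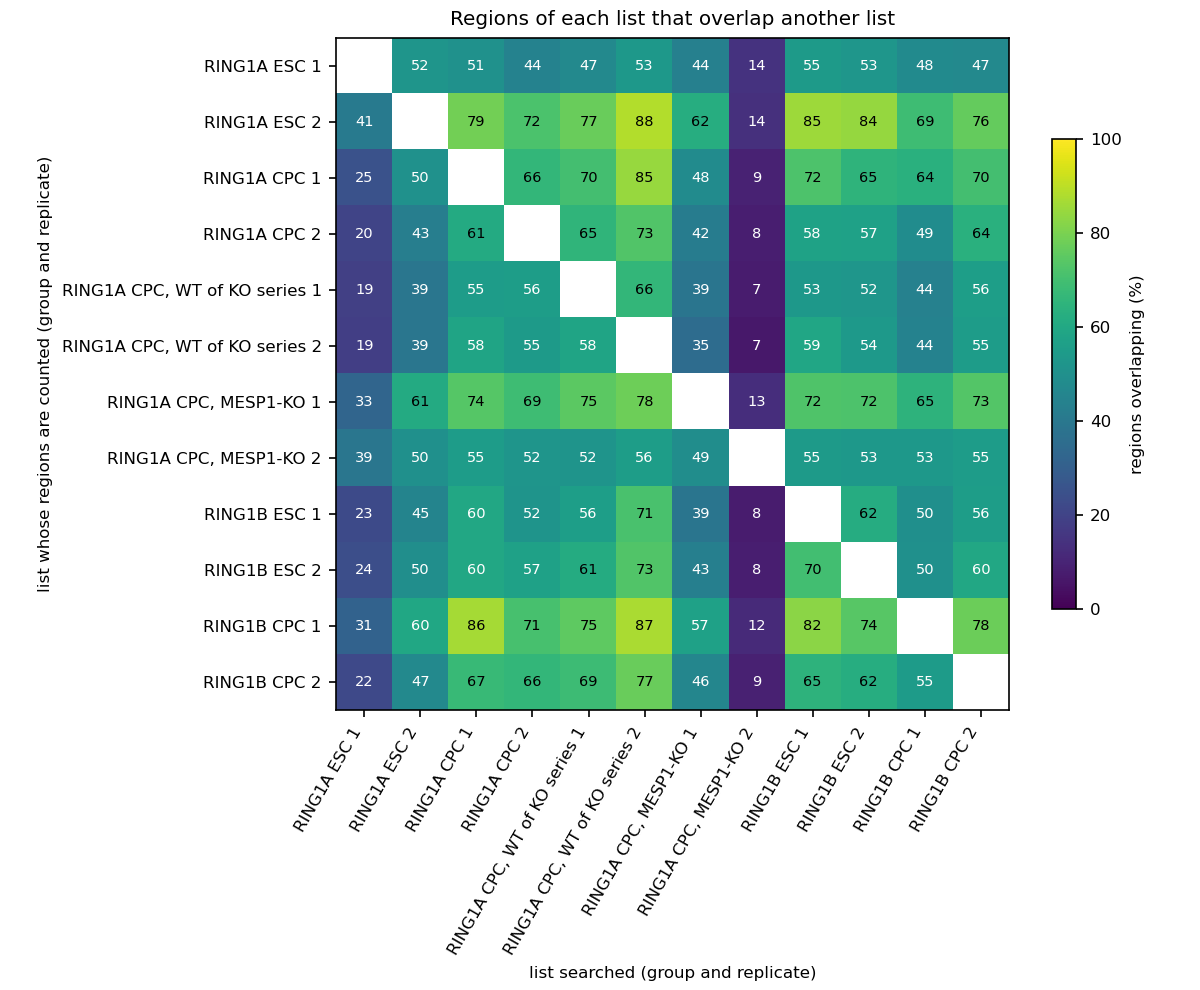
Share of the merged regions of each RING1A or RING1B list (vertical axis, group and replicate) that overlapped another list (horizontal axis), in percent. Knockout replicate 2, the shortest list with 2728 regions, overlapped 7.45% and 6.62% of the regions of the wild-type lists.

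To ask where RING1A sat before and after cardiac specification, ESC and CPC lists were compared. Of 2905 consensus RING1A regions in ESC, 2594 (89.3%) were also called in at least 1 CPC list, and 311 were not. In CPC there were 7122 consensus regions, of which 2416 (33.9%) were called in neither ESC list. Most gained regions were already RING1B regions in ESC: 69.0% of them overlapped an ESC list of RING1B, against 98.3% of RING1A regions present in both stages. H3K27ac, a mark of active promoters and enhancers, covered 69.6% of gained RING1A regions and 52.4% of those in both stages, and FLAG-MESP1 covered 19.4% and 14.3%. H3K4me3, a mark of active and poised promoters, covered 87.7% and 97.0%. Lost RING1A regions carried little of these CPC marks, with H3K4me3 at 20.6%, H3K27ac at 20.9% and FLAG-MESP1 at 3.54%.

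Within classes of region strength, gained RING1A regions had higher odds of carrying H3K27ac (odds ratio 1.87, 95% interval 1.67 to 2.09, Cochran-Mantel-Haenszel adjusted p 9.3e-28) and FLAG-MESP1 (1.56, 1.35 to 1.80, adjusted p 1.3e-09) than those in both stages. Among the stronger 50% of each list the FLAG-MESP1 odds ratio was 1.30 and missed the threshold (p 0.054). Absence from lists of the same stage, examined after the data were seen, also had odds ratios at FLAG-MESP1 sites, which went with the library. Among wild-type RING1A regions of the knockout experiment, absence from RING1A replicate 1 in CPC, as deposited, had a value of 1.58, and absence from replicate 2 a value of 0.910. Absence from both had 1.23 (1.02 to 1.49). With the lists shortened to the knockout lengths, the values were 1.53 and 1.57 when replicate 1 was the longer list and 0.967 and 1.02 when it was the shorter. At H3K27ac regions, absence from both lists had 1.35 (1.14 to 1.60) as deposited and 1.07 to 2.31 when shortened. The 1.87 at gained regions lay within that range, though the ESC lists had other lengths than the knockout lists. Gained regions were narrow. Of 3280 RING1A regions in CPC under 1000 bp wide, 51.2% were gained, against 4.07% of 615 regions of 3000 to 10000 bp and 0 of 204 wider ones. Without ESC replicate 2, 67.3% were gained and 52.5% kept; 55.8% were gained without CPC replicate 1 and 20.9% with equal numbers of regions per list. From the ESC side, 50.7% of ESC replicate 1 regions lay in CPC replicate 1, whose list name carries the same date. In CPC replicate 2 lay 44.4%, against 52.2% in ESC replicate 2. For ESC replicate 2, 78.8% and 71.8% lay in CPC replicates 1 and 2 and 41.0% in ESC replicate 1. From the CPC side the overlap between stages was below that of replicates, with 20.5% to 50.5% of the regions of a CPC list in an ESC list against 66.4% and 61.3% between CPC replicates. The ESC lists were the shorter ones.

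The strongest RING1A region gained in CPC was on chromosome 9 from 110581924 to 110582911, with fold enrichments of 30.0 and 19.8 in the 2 libraries. It was also the strongest region gained by RING1B (chromosome 9, 110581618 to 110582873, fold enrichments 22.8 and 18.2), and carried neither H3K4me3 nor H3K27ac. Next by rank were chromosome 9 from 99982193 to 99984895, with H3K4me3 and H3K27ac, and chromosome 10 from 119589625 to 119591521, with neither mark and also gained by RING1B. The others were chromosome 1 from 78702692 to 78703891 and chromosome 19 from 49630938 to 49631666. Each of these 5 regions carried RING1B in CPC and none carried FLAG-MESP1. Among lost regions the strongest was on chromosome 1 from 2433306 to 2439013. Another 2 of the 5 lay near it on that chromosome, from 2401804 to 2410109 and from 2247254 to 2255047. A wide lost region on chromosome 9, from 137261881 to 137279795, carried H3K27ac and FLAG-MESP1 in CPC, and the remaining one lay on chromosome 18 from 12086039 to 12089321. Fold enrichments of the lost regions in ESC replicate 1 ranged from 6.48 to 8.86.

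**Figure D2:**
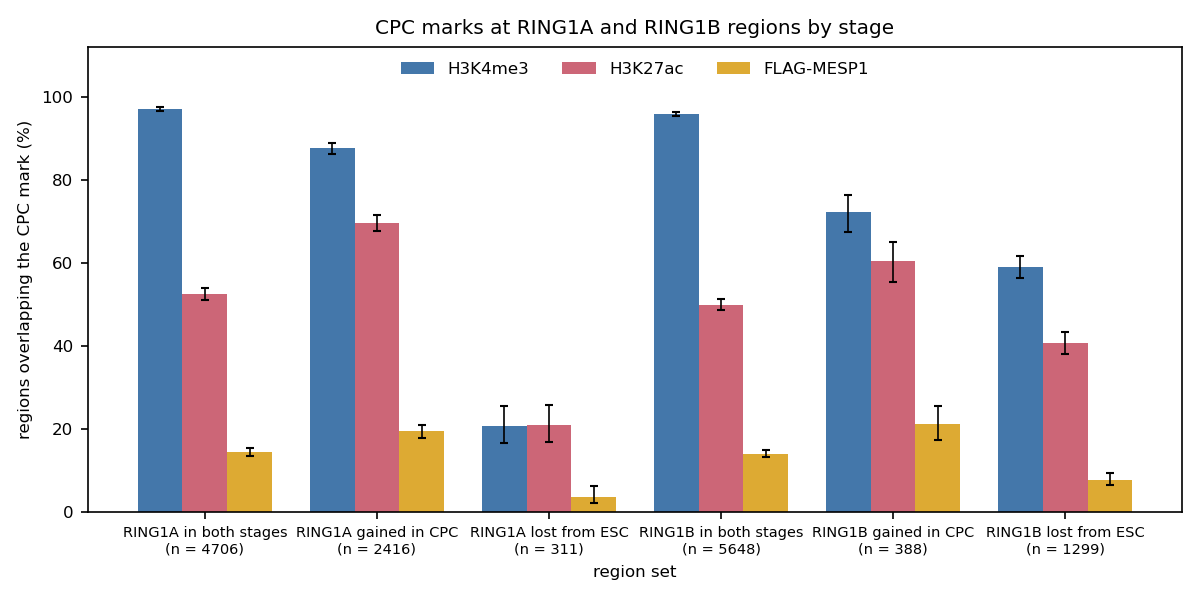
Percentage of RING1A and RING1B consensus regions that overlapped CPC consensus regions of H3K4me3, H3K27ac or FLAG-MESP1, by stage; bars are shares of the number of regions under each set and error bars are Wilson 95% intervals. H3K27ac stood at 69.6% of gained RING1A regions and 52.4% of those in both stages.

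RING1B had fewer consensus regions in CPC than in ESC. Of 7768 consensus RING1B regions in ESC, 6469 (83.3%) were called in at least 1 CPC list and 1299 were absent from both, while 388 of 6036 CPC regions (6.43%) were gained. Lost RING1B regions carried H3K4me3 at 59.0% and H3K27ac at 40.6% in CPC, against 95.9% and 49.9% of regions in both stages. Gained RING1B regions carried H3K27ac at 60.3% and FLAG-MESP1 at 21.1%, with odds ratios within strength classes of 1.23 (0.992 to 1.53, adjusted p 0.061) and 1.58 (1.21 to 2.06, adjusted p 0.00072). For H3K27ac, 11 of 13 alternatives passed the threshold above 1, up to 1.99 (p 2.7e-08) with H3K4me3 held, and the value was 0.972 (p 0.69) without RING1B CPC replicate 2. For FLAG-MESP1 the value was 0.869 (p 0.2) without FLAG-MESP1 replicate 2, 1.17 (p 0.1) without RING1B CPC replicate 2 and 1.17 (p 0.51) among the stronger 50% of each list. The gained share rose to 27.0% without RING1B CPC replicate 1, to 13.5% without CPC replicate 2 and to 14.6% without ESC replicate 1, and was 12.6% with equal numbers of regions. Within the same date, 49.9% of ESC replicate 1 regions lay in CPC replicate 1 and 59.9% of ESC replicate 2 regions in CPC replicate 2, giving 54.9% for the average over same-numbered pairs. These were below the replicate overlaps in ESC of 62.1% and 69.6%. In the opposite direction the order turned: 82.4% of CPC replicate 1 regions lay in ESC replicate 1 and 62.5% of CPC replicate 2 regions in ESC replicate 2, above the replicate overlaps in CPC of 77.7% and 54.9%.

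Besides the region on chromosome 9, the strongest RING1B gains were on chromosome 2 from 114263665 to 114264207, chromosome 10 from 119589114 to 119591622, chromosome 3 from 151976743 to 151982492 and chromosome 15 from 69846673 to 69847289. None of these 5 carried H3K4me3 or H3K27ac. Strongest among RING1B losses was chromosome 11 from 20220199 to 20223950, with fold enrichments of 34.8 and 14.8 in ESC, and the only one of 5 with FLAG-MESP1. The others were chromosome 4 from 8359779 to 8361412, chromosome 11 from 65226917 to 65227366, chromosome 20 from 32155984 to 32156755 and chromosome 19 from 1774993 to 1777723.

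Most RING1A regions were also RING1B regions. In CPC 4959 of 7122 RING1A regions (69.6%) held a consensus RING1B region, against 0.913% ± 0.143 (SD) after circular shifts (adjusted p 0.0012, from the smallest p that the shifts can give). The share was 89.1% of 2905 regions in ESC, against 1.36% ± 0.290 (SD) after shifts (adjusted p 0.0012). With equal numbers of strongest regions in the RING1A and RING1B lists of a stage, the shares were 77.5% in CPC and 79.1% in ESC. The gap between stages thus depended on list lengths. The shifts test overlap against random placement along a chromosome only. They do not hold H3K4me3, which most CPC regions of both factors carried. From the RING1B side, 80.9% of 6036 CPC regions held RING1A, while in ESC between 22.6% and 49.5% of the regions of a RING1B list lay in one of the shorter RING1A lists. In CPC 603 RING1A regions overlapped neither RING1B list, and these carried H3K27ac at 72.8% against 51.4% of shared regions. The reverse set, RING1B without RING1A, held 163 regions with H3K27ac at 33.7%. The difference between these sets was not tested. Without RING1A CPC replicate 1 the share with RING1B was 45.5%, and without RING1A ESC replicate 2 it was 51.3% in ESC.

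PRC1 regions in CPC lay mostly at H3K4me3. Of RING1A regions 93.9% carried H3K4me3 and 56.4% carried H3K4me3 with H3K27ac. RING1B regions carried H3K4me3 at 94.4% and both marks at 49.5%. Wide domains carried less H3K27ac, with 34.8% of the 204 RING1A regions of 10000 bp or more against 64.8% of those under 1000 bp. The widest 5, chosen after their values were seen, were on chromosome 17 from 46644539 to 46714493, chromosome 7 from 27159016 to 27220491, chromosome 5 from 92904248 to 92957484, chromosome 15 from 96860639 to 96913506 and chromosome 2 from 176936170 to 176981367. Each of the 5 carried H3K4me3 and RING1B. Those on chromosomes 17 and 15 also carried H3K27ac, and those on chromosomes 7 and 5 carried FLAG-MESP1.

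Whether MESP1 and RING1A meet at the same sites was asked with FLAG-MESP1 in CPC. There were 15012 consensus FLAG-MESP1 regions, of which 10405 (69.3%) had neither H3K4me3 nor H3K27ac. RING1A was found at 1145 of them (7.63%), against 0.796% ± 0.0747 (SD) after circular shifts. Of FLAG-MESP1 replicate 1 regions 12.9% had RING1A, and of replicate 2 regions 4.05%. These 1145 regions carried active marks, with H3K4me3 at 95.3% and H3K27ac at 84.9%, and RING1B at 64.4%. Over 25688 H3K27ac regions of wild-type CPC, RING1A was more frequent where FLAG-MESP1 was present, with an odds ratio pooled over H3K4me3 presence of 1.36 (1.25 to 1.48, Cochran-Mantel-Haenszel adjusted p 3.2e-12). With H3K4me3 the RING1A shares were 33.4% of 2905 regions with FLAG-MESP1 and 27.1% of 11180 without. Away from H3K4me3 they were 1.94% of 1237 and 1.03% of 10366. Over H3K4me3 regions in place of H3K27ac regions the odds ratio was 1.09 (1.01 to 1.18).

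The size of this association depended on the MESP1 library. Odds ratios for single pairs of libraries were 2.70 and 3.75 with FLAG-MESP1 replicate 1 and 1.30 and 1.51 with replicate 2, and the consensus value without FLAG-MESP1 replicate 2 was 2.81. Replicate 1 had H3K4me3 at 37.2% of its regions and replicate 2 at 13.7%. The strongest FLAG-MESP1 regions, by mean width rank over the libraries, were on chromosome 1 from 87614707 to 87622962, chromosome 9 from 2353967 to 2362159, chromosome 7 from 45250846 to 45257593, chromosome 18 from 34044836 to 34051512 and chromosome 15 from 42119761 to 42126389. None of these 5 carried RING1A or RING1B, and those on chromosomes 1 and 15 carried both histone marks.

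To see whether RING1A sites need MESP1, wild-type and MESP1-knockout CPC were compared. Of 9029 consensus RING1A regions in wild type, 3906 (43.3%) were called in neither knockout list, and 2 of 943 consensus knockout regions (0.212%) were absent from wild type. Lost regions carried H3K27ac at 78.0% and FLAG-MESP1 at 21.1%, against 54.4% and 15.1% of retained regions. RING1B in CPC was present at 27.4% of lost and 79.6% of retained regions. Of 734 regions of 3000 to 10000 bp, 3.00% were lost, and 0 of 215 wider regions, against 70.7% of 3428 regions under 1000 bp. The lost share was 89.2% when knockout replicate 1 was left out, 44.1% without knockout replicate 2, and 64.1% without wild-type replicate 1. It was 18.0% of 1694 consensus regions with an equal number of widest regions per list, and 77.2% as the average over same-numbered pairs, which share dates. The 18.0% is of a set chosen for width, and wide regions were seldom lost, so it is no share of the 9029 regions. For scale, 66.4% of wild-type replicate 1 regions were found in wild-type replicate 2, and 9.75% of the 9029 regions were absent from both lists of the other wild-type RING1A experiment. Those lists were longer than the knockout lists. Shortened to the knockout lengths, they lacked 33.5% to 39.0% of the 9029 regions, depending on library and ranking.

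RING1A loss was more frequent at MESP1 sites. Of 1599 wild-type regions with FLAG-MESP1, 826 (51.7%) were lost, against 3080 of 7430 without (41.5%). Within width classes the pooled odds ratio was 1.79 (1.57 to 2.04, adjusted p 2.4e-18). In the narrowest class 86.2% were lost with and 78.1% without FLAG-MESP1, and in the widest class 11.9% and 7.39%. For single pairs of libraries the odds ratio ranged from 1.25 to 2.17. Loss was also more frequent at H3K27ac regions (odds ratio 2.98, 2.67 to 3.34, adjusted p 6.1e-85) and at regions called in neither ESC list (4.77, 4.29 to 5.31, adjusted p 2.5e-198). Without knockout replicate 1 the H3K27ac value was 1.87, and 4.57 with equal numbers of regions. For regions absent from ESC it was 8.35 without wild-type replicate 2 and 9.25 without strength classes. The same odds ratios were taken, after the data were seen, for absence from the other wild-type RING1A lists of CPC. At regions absent from ESC they were 3.32 (2.75 to 4.01) with the lists as deposited and 2.00 to 3.94 when shortened to the knockout lengths. At H3K27ac regions they were 1.35 (1.14 to 1.60) as deposited and 1.07 to 2.31 when shortened. Both knockout values were above these, and the interval of the highest wild-type value for regions absent from ESC, 3.55 to 4.37, overlapped that of the knockout. At FLAG-MESP1 sites the wild-type values were 1.23 (1.02 to 1.49) as deposited and 0.967 to 1.57 when shortened. The interval of the highest, 1.37 to 1.79, overlapped the 1.57 to 2.04 of the knockout.

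**Figure D3:**
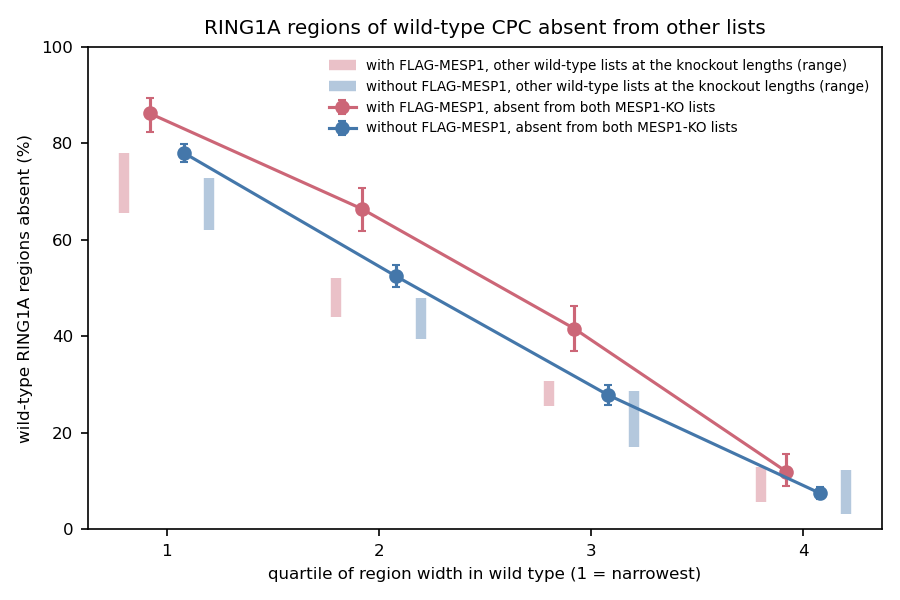
Percentage of wild-type RING1A consensus regions with and without FLAG-MESP1 that were absent from both MESP1-knockout lists (filled points, Wilson 95% intervals) and range of that percentage over 4 ways of shortening the other wild-type RING1A lists to the knockout lengths (pale bars), by quartile of region width. Loss in the knockout lists fell from 86.2% to 11.9% at FLAG-MESP1 sites and from 78.1% to 7.39% elsewhere. The ranges for shortened wild-type lists lay between 65.6% and 78.0% at the narrowest FLAG-MESP1 sites and between 62.1% and 72.8% at the narrowest others. In quartile 4 the knockout values lay inside the ranges, 5.56% to 13.0% with and 3.03% to 12.2% without FLAG-MESP1. In quartile 3 without FLAG-MESP1, 27.8% also lay inside 17.0% to 28.7%. The other knockout values lay above their ranges.

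The strongest of the lost RING1A regions, by mean width rank over the libraries, was on chromosome 14 from 69258838 to 69263429, with H3K4me3, H3K27ac, FLAG-MESP1 and RING1B. It was followed by chromosome 3 from 64670729 to 64674474, chromosome 9 from 109622323 to 109626039, chromosome 7 from 127670361 to 127673395 and chromosome 17 from 46100791 to 46104205. Each of these 5 carried H3K4me3, and the region on chromosome 7 lacked H3K27ac. The 2 regions called in both knockout lists and in neither wild-type list were on chromosome 21 from 47486513 to 47487826 and chromosome 3 from 11195851 to 11196440, with fold enrichments between 3.24 and 4.22. The gained share was 43.7% without knockout replicate 1, 17.6% without knockout replicate 2, 1.80% and 0.530% without wild-type replicates 2 and 1, and 8.70% with equal numbers of regions.

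The effect of losing RING1A on active chromatin was examined with H3K27ac in wild-type and RING1A-knockout CPC. Of 25688 wild-type consensus regions, 3986 (15.5%) were called in neither knockout list, and 2128 of 22623 knockout regions (9.41%) were absent from wild type. Lost and gained regions lay mostly away from H3K4me3, which covered 12.8% of lost, 62.5% of retained and 10.2% of gained regions. Changes fell on weak regions: 38.9% of the weakest strength class were lost and 0.0467% of the strongest. Between single lists, overlaps across genotypes ranged from 56.6% to 76.1% and those of replicates from 70.1% to 80.1%. Knockout replicate 1 regions lay in the wild-type lists at 71.7% and 76.1%, and in knockout replicate 2 at 71.4%. For each of the other lists the overlap with its replicate was the higher. The lost share was 27.8% without knockout replicate 1, 31.0% without wild-type replicate 1 and 26.1% without wild-type replicate 2, and 36.7% as the average over same-numbered pairs. No date was shared across genotypes, so date and genotype cannot be told apart. The gained share was 26.2% without knockout replicate 1, 18.6% without knockout replicate 2 and 16.1% without wild-type replicate 2.

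RING1A sites lost H3K27ac less often than other sites. The odds ratio of loss within strength classes was 0.427 at RING1A regions (0.362 to 0.505, adjusted p 1.7e-23), and RING1A covered 4.39% of lost and 18.3% of retained regions. When classes were also split by H3K4me3, the value was 1.08 (0.892 to 1.30, p 0.44), so the direction did not hold among regions alike in that mark. H3K27ac gain at RING1A sites behaved the same way, at 0.348 (0.274 to 0.442, adjusted p 4.7e-19) and 1.12 (p 0.44) with H3K4me3 held. At H3K4me3 regions the odds ratio of loss was 0.277 (0.250 to 0.307, adjusted p 2.2e-150), 0.460 without H3K4me3 replicate 1 and 0.160 among the stronger 50% of each list. Without strength classes the odds ratio of loss was 0.206 at RING1A and 0.0881 at H3K4me3 regions, and that of gain at RING1A regions 0.171. Without RING1A CPC replicate 1 the loss at RING1A regions was 0.652, and without knockout replicate 1 the gain there was 0.214.

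At MESP1 sites H3K27ac loss had an odds ratio of 0.808 (0.709 to 0.922, adjusted p 0.0015). This turned to 1.19 (p 0.077) among the stronger 50% of each list. It was 0.980 (p 0.7) without knockout replicate 1, 0.889 (p 0.1) with the stricter FLAG-MESP1 list, 0.396 without FLAG-MESP1 replicate 2 and 0.421 without strength classes. H3K27ac gain at MESP1 sites had an odds ratio of 0.395 (0.312 to 0.499, adjusted p 1.2e-15), and 0.195 without strength classes. By definition, gained regions lie outside the wild-type H3K27ac lists. FLAG-MESP1 regions overlapped wild-type H3K27ac regions at 28.1%, against 2.84% after circular shifts. A value below 1 was therefore likely beforehand and says little about losing RING1A.

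**Figure D4:**
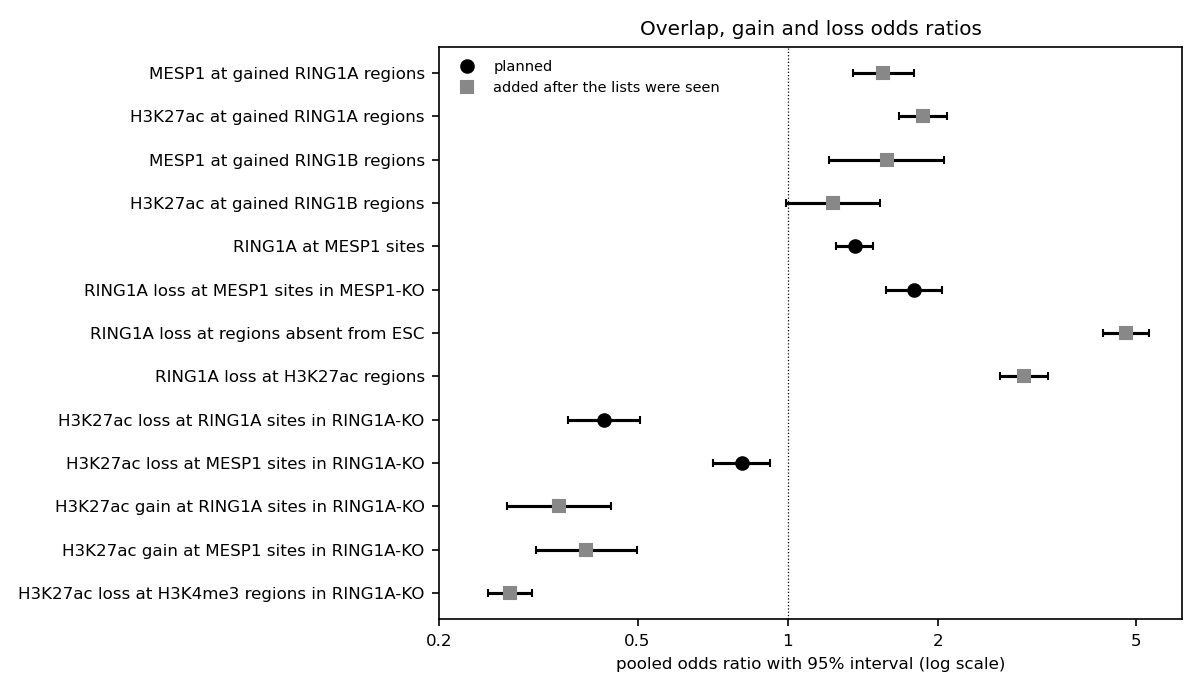
Pooled odds ratios with 95% intervals on a log scale for overlap, gain and loss; circles were planned and squares were added after the lists were seen. RING1A loss at MESP1 sites stood at 1.79 before H3K27ac was held, and H3K27ac loss at RING1A sites at 0.427 before H3K4me3 was held.

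Among lost H3K27ac regions the strongest was on chromosome 16 from 58065089 to 58067922, with fold enrichments of 23.4 and 21.2 in wild type. The others were chromosome 15 from 23809978 to 23811419, chromosome 16 from 83422482 to 83426754, chromosome 2 from 179701191 to 179703184 and chromosome 12 from 54768176 to 54773579. The region on chromosome 2 carried FLAG-MESP1, and none of the 5 carried RING1A. Gained regions were weaker, with fold enrichments of 8.34 and 14.9 on chromosome 3 from 48148069 to 48149427. The next were chromosome 11 from 73494027 to 73496758 and from 77159948 to 77160599, and chromosome 2 from 242031750 to 242034734 and from 168715937 to 168720147. None of these 5 carried H3K4me3, RING1A or RING1B, and the region ending at 242034734 carried FLAG-MESP1.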

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

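The test in this part was chosen after the lists were seen. H3K27ac set gained regions apart from those in both stages more for RING1A than for RING1B. The odds ratio was 1.87 for RING1A and 1.23 for RING1B, a ratio of 1.52 (p 0.00081, from the difference of the log odds ratios). That p treats the region sets of the factors as independent, although many regions are shared. As given above, absence from RING1A lists of the same stage, shortened to the knockout lengths, gave 1.07 to 2.31 at H3K27ac regions. The RING1A value of 1.87 lies within that range, so it need not mark a change of stage. The RING1B value was among the lowest of its alternatives, 11 of 13 of which passed the threshold above 1. Over 19 alternatives the ratio stayed above 1, from 1.10 to 2.09, and 12 of the 19 passed 0.05. It was 1.20 (p 0.2) with H3K4me3 held, 1.15 (p 0.28) with equal numbers of regions, 1.13 (p 0.43) among the stronger 50% of each list and 1.10 (p 0.43) without RING1A CPC replicate 2. Without RING1B ESC replicates 1 and 2 it was 1.20 (p 0.061) and 1.15 (p 0.22). For FLAG-MESP1 the same ratio was 0.986 (p 0.93).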

How the results depend on the processing

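Alternatives for strata with H3K27ac, deciles of strength and a q filter on knockout replicate 2, and absence from other wild-type lists, were chosen after seeing the data, as were the 9 added tests, the shares of gained regions and their alternatives; the rest were planned. Of 130 alternative values for the 10 planned results, 110 kept their direction and side of the threshold, or stayed within the spread of list pairs. That spread (SD over 4 list pairs) was 16.5 percentage points for RING1A kept, 17.4 for RING1A lost, 4.81 for RING1B kept and 5.62 for H3K27ac lost. Some alternatives repeat the main values. Another list of RING1A CPC replicate 1 gave the same regions once merged, and RING1A lost was 43.3% with and without merging. RING1A at MESP1 sites kept its call in its 19 alternatives (1.09 to 2.81; lowest with H3K4me3 regions as universe, p 0.032) and RING1A loss at MESP1 sites in its 16 (1.35 to 2.25). RING1A with RING1B kept its call in 11 alternatives in CPC (45.5% to 85.7%) and in 9 in ESC (51.3% to 91.6%). That call could hardly fail, since shifts along whole chromosomes gave 0.913% in CPC and 1.36% in ESC in the main setting. These alternatives count among the 110 but say little about robustness.

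Loss of RING1A in the MESP1 knockout was 18.0% of 1694 consensus regions with an equal number of widest regions per list. It was 78.5% of the 9029 regions with the list of the first run in place of the main list of knockout replicate 1. Knockout replicate 2 was still used there. These shares are of different sets, and the first was chosen for width. H3K27ac loss at RING1A sites turned to 1.08, and gain there to 1.12, with H3K4me3 held. H3K27ac loss at MESP1 sites turned to 1.19 among the stronger 50% of each list and was 0.889 with the stricter FLAG-MESP1 list. Leaving out single libraries gave 52.5% to 87.5% for RING1A kept, 62.7% to 76.8% for RING1B kept, 44.1% to 89.2% for RING1A lost, 18.0% to 31.0% for H3K27ac lost and 0.396 to 0.980 for H3K27ac loss at MESP1 sites. It also gave 0.869 to 1.60 for FLAG-MESP1 and 0.972 to 1.63 for H3K27ac at gained RING1B regions. Leaving out a library shortens what a region must meet, which by itself moves these shares; the other causes were not tested.

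With the replicate block (same-numbered pairs, averaged) RING1A kept was 61.2%, RING1B kept 54.9%, RING1A lost 77.2% and H3K27ac lost 36.7%. These pairs compare single lists, so they count a region as absent after 1 list and not after 2. Promoter counts and their windows were not run, because no hg19 annotation was used here. Unknown read depth limits every absence to "not called".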

Other observations

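Tests in this part chosen after the result was seen are those on knockout replicate 1 alone, on the strongest regions of knockout replicate 2, on absence from other wild-type lists, shortened or as deposited, with H3K27ac held and within 10 classes of H3K27ac strength. FLAG-MESP1 regions overlapped H3K27ac at 28.1% and H3K4me3 at 22.0%, against 2.84% and 2.90% after circular shifts (p 0.001 for each, the smallest possible). RING1A regions lost in the MESP1 knockout overlapped RING1B in ESC at 68.0%, against 96.3% of retained regions. Of lost H3K27ac regions in the RING1A knockout 7.58% had RING1B in ESC, against 31.9% of retained regions.

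Fewer RING1A regions were called in the MESP1 knockout. With 2728 widest regions per list, the overlap between wild-type lists exceeded the overlaps with knockout lists by 0.660 to 42.3 percentage points, and by at most 0.990 for knockout replicate 1. These shortened wild-type lists held 13.4% of the lost regions, which were mostly narrow, so the small gap does not separate lower yield or stricter calling from an effect of the genotype. Of the 500 strongest regions of knockout replicate 2, 95.6% and 98.2% were found in the wild-type lists, against 41.9% and 46.0% of its other 2228, consistent with many weak calls in that list. List names put a stricter threshold on wild-type replicate 2 than either knockout list shows, which leaves yield and genotype open.

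RING1A loss was more frequent at MESP1 sites. Differences between width classes could hardly be the whole cause, since FLAG-MESP1 sites spread almost evenly over them (378, 420, 423 and 378 regions). Holding the classes was therefore no strict test. The odds ratio was 1.51 without them, and its lower bound was 1.57 within them. Region strength stays open, since the wild-type lists of this comparison hold no peak values and width stood in for it. Differences in width or signal within a class were not held. Promoter chromatin stays open: with H3K4me3 also held the bound was 1.58, but 95.8% of the regions carried that mark, so holding it could move little, and with H3K27ac held the odds ratio was 1.36 (1.19 to 1.56). Whether lists miss MESP1 sites in any genotype stays open. Absence from both other wild-type RING1A lists of CPC gave 1.23 (1.02 to 1.49) as deposited. Shortened to the knockout lengths, these lists gave 1.53 and 1.57 with replicate 1 the longer list, and 0.967 and 1.02 with it the shorter. Absence from single lists as deposited gave 1.58 for replicate 1 and 0.910 for replicate 2, so the values went with the library. RING1B in CPC gave 1.64 and 1.35, and RING1A in ESC 1.92 and 2.02. Such differences between libraries and the genotype cannot be told apart. Single day 4 lists from cells with MESP1 intact gave 0.910 to 1.64, against 1.77 and 1.35 for knockout replicates 1 and 2. Only the ESC lists reached 1.79, the value for absence from both knockout lists. They are from day 0, so they are no control for genotype.

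RING1A was more frequent at H3K27ac regions with MESP1. Differences in H3K27ac peak value are argued against as the whole cause, since the lower bound was 1.21 within 10 classes of that value split by H3K4me3. Region width was not held, so wide regions that hold every mark stay open. With H3K4me3 regions as the universe the odds ratio was 1.09 (1.01 to 1.18). The difference between FLAG-MESP1 libraries stays open, and binding of the overexpressed protein may differ from that of native MESP1, which was not tested.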
